A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

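Gene expression was measured on 13 arrays of RNA from Saccharomyces cerevisiae, the haploid laboratory strain BY4741, grown to mid-log phase in YPD, a rich medium, and treated for 30 min. Per the labels, total RNA was extracted with the RiboPure-Yeast kit and its quality was checked on a Bioanalyzer. Biotin-labelled cRNA was made with One-Cycle Target Labeling and hybridised to one-colour Affymetrix yeast arrays. SMERs are small molecule enhancers of rapamycin, compounds known by code names. Rapamycin is an inhibitor of TOR complex 1, a kinase complex that couples growth to nutrients. The groups were DMSO, the solvent control (3 arrays), rapamycin at 100 nM (2 arrays), SMER1 at 20 µM (2 arrays), SMER1 at 20 µM with rapamycin at 100 nM (2 arrays), and SMER2, SMER3, SMER4 and SMER5 at 20 µM (1 array each). The labels number the replicates but do not say whether they were separate cultures.

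The deposited values were log2 signal intensities of 5716 probe sets, and the log2 scale was judged from their range, 0 to 14.67. How the authors summarised probes into probe sets, corrected background and normalised arrays was not given in the sources used here. The median of the deposited log2 values lay between 10.99 and 11.07 on the 13 arrays. The sorted columns were not identical, so the probe set values had not been left in a quantile-normalised state. This check cannot show whether quantile normalisation was applied at an earlier step, before probes were summarised. Of all values, 4 were 0 and 1383 lay below 5. The small number of arrays limits the precision of every value.

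Probe sets were matched to genes through a table of probe set names, with 12 symbols updated from the R64 gene table. Of the 5716 probe sets, 5498 had 1 gene name and 218 had none, and the latter were left out of the comparisons. For the 47 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 5449 genes. Of these, 115 were measured by probe sets whose names mark them as shared between similar transcripts. The R64 table served for names and gene order only, and no coordinates were used here.

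The log2 values were used as deposited. A linear model with 1 mean per group for all 8 groups was fitted to each gene with limma 3.58.1 in R 4.3.3, and the variances were moderated by eBayes (residual degrees of freedom 5, prior degrees of freedom 2.36, prior SD 0.102). A gene was called when its Benjamini-Hochberg adjusted p over the 5449 genes was under 0.05. All tests were two-sided unless stated. A lone array was assumed to vary like the arrays of the replicated groups, and its difference from DMSO had no replicate check. Each SMER, rapamycin, and SMER1 with rapamycin were compared with DMSO. SMER1 with rapamycin was also compared with rapamycin alone. The interaction compared the effect of SMER1 in the presence and in the absence of rapamycin. For each SMER, genes called with the same sign against DMSO and against rapamycin were counted. A moderated F test asked whether a gene differed among the 5 SMERs.

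The following 31 gene lists were tested for shifts: the sulfur amino acid regulon (Met4 targets), nitrogen catabolite repression (Gln3 and Gat1 targets), the retrograde response, cytosolic ribosomal proteins, ribosome biogenesis factors, subunits of RNA polymerases I and III, the general stress response (Msn2 and Msn4 targets), Hsf1 targets, Yap1 targets, pleiotropic drug resistance (Pdr1 and Pdr3 targets), Gcn4 targets, the iron, zinc and phosphate regulons, ergosterol biosynthesis, the proteasome, the DNA damage response, the unfolded protein response, G1/S genes, core histones, G2/M genes, M/G1 daughter genes, mitochondrial respiration and ATP synthase, gluconeogenesis with the glyoxylate cycle and beta-oxidation, autophagy, glucose transport and glycolysis, purine biosynthesis, a-cell genes, alpha-cell genes, pheromone response, and meiosis and sporulation. A further list held the 4 genes altered in BY4741. The lists were tested with limma camera, which asks whether a list's genes shift relative to all other genes, at its preset correlation of 0.01, with adjustment over the 31 lists within each comparison. The same test with the correlation estimated from the data was run beside it. The rotation test fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. For the lone arrays, the list median was also placed among the medians of 10000 random lists matched on expression in 20 bins. Counts of called list members are given over all genes, and where stated adjusted over the list alone. These groups, comparisons, tests and lists were chosen before the data were examined. The comparisons of SMER3 with SMER1 and of SMER4 with SMER5, the list tests of the first of these and of the interaction, and the counts of list members called against both references were added afterwards.

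Genes to be named were also fixed before the data were examined. For each comparison they were the 8 largest rises and 8 largest falls among called genes whose treated arrays all lay on the same side of every control array (for the interaction, the largest called values), up to 4 called members with the largest change of each list, and the 10 genes with the smallest p of the F test. URA3, LEU2, MET17 and HIS3 were named in every case. A member of a list that is named outside this rule, and the families in the closing section, were chosen after their values were seen.

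Shared calls between a SMER and rapamycin were set beside the number expected if the calls were independent. The covariance of log2 fold changes across genes was set beside 50 simulated sets of unchanged arrays compared with the same DMSO arrays. The 3 DMSO arrays could not be divided into parts of 2 arrays each.

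The fit was tested on simulated data with the same groups, in which 200 genes were changed. At a change of log2 0.5 the fit recovered 64.2% of the changed genes in the groups of 2 arrays and 35.8% in SMER4, and at log2 1 it recovered 98.5% for rapamycin, 89.6% for SMER1, 94.0% for both drugs and 85.1% for SMER4. Between 7 and 14 unchanged genes were called per comparison. A list shifted by 0.5 was called in each of the 4 comparisons tested, with 0 of the 30 other lists called by camera. The simulated noise was independent between genes, so this does not test the list calls where genes of a list vary together.

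The alternatives were quantile normalisation, leaving out the 25% of genes with the lowest mean, an intensity trend in eBayes, a replicate block, fits with only the arrays of the groups compared, and leaving out each array of a replicated group in turn. Replicates were not treated as paired. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.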

Results

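The series measured mRNA on 13 arrays of yeast treated for 30 min with a drug or solvent: DMSO (n = 3), rapamycin (n = 2), SMER1 (n = 2), SMER1 with rapamycin (n = 2), and SMER2, SMER3, SMER4 and SMER5 (n = 1 each). The stated purpose was to compare each SMER with the solvent and with rapamycin, to find expression signatures particular to the SMERs. Values are log2 signal intensities, differences are log2 fold changes, and ± gives the standard error of a difference from limma. Arrays of a group correlated across genes with r between 0.984 and 0.992, and arrays of different groups with r between 0.801 and 0.995. The median SD between arrays of a group was 0.11 in DMSO, 0.09 in SMER1, 0.07 in SMER1 with rapamycin and 0.08 in rapamycin.

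The marker genes altered in BY4741 were read as a check of the strain. URA3 lay between 1.97 and 4.55 on the 13 arrays, MET17, an enzyme of homocysteine synthesis, between 4.05 and 5.78, and LEU2 between 6.29 and 8.61. The lowest LEU2 value was that of the lone SMER3 array, and the next lowest, in SMER2, was 7.69. HIS3, which is only partly deleted in this strain, lay between 12.14 and 13.18. The array medians lay near 11.

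Rapamycin raised the genes of nitrogen catabolite repression, which serve the use of poor nitrogen sources. All 22 measured members rose against DMSO, with a median of 4.21 (n = 2 rapamycin and 3 DMSO arrays). DAL80, a GATA repressor of this pathway, rose by 7.37 ± 0.24, the allantoin pathway genes DAL3 and DAL1 by 6.46 ± 0.36 and 5.56 ± 0.15, the oligopeptide transporter gene OPT2 by 5.30 ± 0.17, the proline permease gene PUT4 by 5.08 ± 0.11, and the ammonium permease gene MEP2 by 4.61 ± 0.10. This list's shift was called (adjusted p = 2.23e-11) and was the one among the 13 lists called in this comparison that held with an estimated correlation (adjusted p = 0.0178).

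Ribosome biogenesis and polymerase genes fell with rapamycin, and a smaller share of ribosomal protein genes did. All 101 ribosome biogenesis factors fell, with a median of −1.79, among them RRP5 (−3.20 ± 0.16), RRP36 (−3.05 ± 0.18) and UTP20 (−2.86 ± 0.14). All 20 subunits of RNA polymerases I and III, which transcribe ribosomal and transfer RNA, fell, with a median of −1.49. RPA190 and RPA135, the large subunits of RNA polymerase I, fell by 2.94 ± 0.12 and 2.69 ± 0.23. Of 127 cytosolic ribosomal protein genes, 34 fell (28 adjusted over the list alone), with a median of −0.07. The list medians of the rapamycin arrays (−0.05 and −0.10) lay within those of the DMSO arrays (−0.16 to 0.09). RPL22B fell by 1.10 ± 0.09 and RPS14B by 1.07 ± 0.10. The largest single falls included the RNA helicase gene DHR2 (−3.22 ± 0.17), the acetyltransferase gene KRE33 (−3.13 ± 0.22), both of ribosome assembly, and the uracil permease gene FUR4 (−2.99 ± 0.20). The 3 list shifts were called (adjusted p = 1.32e-39, 2.55e-13 and 2.28e-05) and were not called with an estimated correlation (adjusted p = 0.481, 0.481 and 0.762).

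Stress, autophagy, respiration and proteasome genes rose with rapamycin. Of 30 targets of the general stress factors Msn2 and Msn4, 29 rose, with a median of 1.80, among them SOL4 (2.99 ± 0.12), the transcriptional repressor gene XBP1 (2.92 ± 0.21) and the glycogen phosphorylase gene GPH1 (2.59 ± 0.08). Of 24 autophagy genes, 20 rose, with a median of 1.27, including the vacuolar aminopeptidase gene APE1 (2.36 ± 0.07) and the ubiquitin-like ATG8 (2.16 ± 0.09). All 8 retrograde response genes, which supply 2-oxoglutarate, rose, CIT2 by 1.50 ± 0.11 and PYC1 by 1.33 ± 0.10. Of 35 respiration and ATP synthase genes 29 rose and 1 fell, and of 33 proteasome genes 31 rose, with medians of 0.56 and 0.46. Of 16 purine biosynthesis genes 9 fell and 2 rose, and IMD4, of guanine nucleotide synthesis, fell by 1.62 ± 0.13. The shifts of these 6 lists were called (adjusted p = 4.39e-10, 1.01e-05, 0.000747, 8.82e-05, 3.02e-05 and 0.00409), and with an estimated correlation their adjusted p lay between 0.443 and 0.656. The shifts of Yap1 targets, Gcn4 targets and ergosterol genes (medians 0.36, 0.39 and 0.41; adjusted p = 0.0168, 0.0487 and 0.0168) were lost after quantile normalisation (adjusted p = 0.0665, 0.539 and 0.25) and with an estimated correlation (adjusted p = 0.501, 0.762 and 0.617). The Gcn4 call was also lost when the 25% of genes with the lowest mean were left out (adjusted p = 0.0720), and without DMSO replicate 3, rapamycin replicate 2 or either SMER1 array (adjusted p = 0.0701, 0.0980 and 0.0518).

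The other 18 lists were not called by camera with rapamycin. The sulfur amino acid list had 10 members higher and 5 lower (median 0.28, mean 0.12, test direction down, adjusted p = 0.644). The methionine permease gene MUP1 fell by 1.49 ± 0.11 and the sulfur regulator gene MET28 rose by 1.77 ± 0.21. Within the phosphate regulon (adjusted p = 0.158) the nucleotide phosphatase gene PHM8 rose by 3.83 ± 0.08 and the phosphate transporter gene PHO89 fell by 2.89 ± 0.13. Adjusted p was 0.582 for the zinc regulon, 0.405 for the DNA damage response, 0.582 for the unfolded protein response, 0.582 and 0.620 for a-cell and alpha-cell genes, 0.107 for pheromone response and 0.242 for meiosis genes. None of the first 5 of these lists was called in any comparison with DMSO. Across all genes, 3276 were called by limma, 2165 higher and 1111 lower, and 488 and 349 of them changed at least 2-fold. The median of all genes was 0.16 as deposited and 0.03 after quantile normalisation, which gave 1730 higher and 1489 lower.

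**Figure D1:**
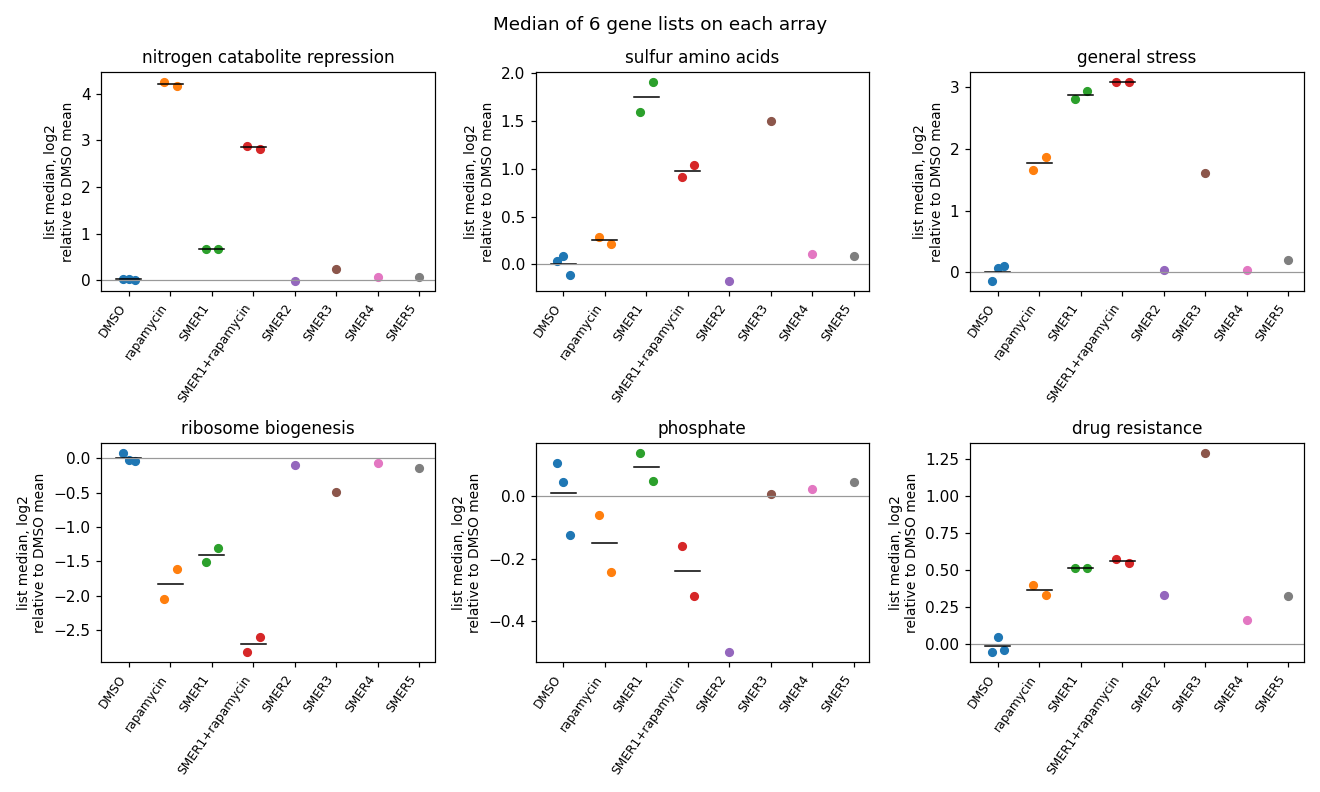
Median log2 signal of 6 gene lists on each of the 13 arrays (y axis, relative to the DMSO mean; 1 point per array, bars for group means) by treatment (x axis). The nitrogen list had a median log2 fold change of 4.21 with rapamycin and 0.69 with SMER1, and the sulfur list of 1.71 with SMER1 and 1.50 with SMER3.

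SMER1 raised sulfur amino acid and stress genes and lowered ribosome biogenesis and G1/S genes (n = 2 SMER1 and 3 DMSO arrays). Of 24 targets of Met4, the activator of sulfate assimilation and methionine synthesis, 22 rose, with a median of 1.71. The sulfate permease gene SUL1 rose by 4.55 ± 0.52, the cystathionine beta-lyase gene STR3 by 3.54 ± 0.31, the homoserine acetyltransferase gene MET2 by 3.28 ± 0.17 and MET28 by 3.02 ± 0.21. All 30 general stress genes rose, with a median of 2.84, including XBP1 (4.52 ± 0.21), RTN2 (4.44 ± 0.21) and the aldehyde dehydrogenase gene ALD3 (4.32 ± 0.18). Of 22 targets of Yap1, the oxidative stress factor, 20 rose, with a median of 0.87, including the peroxiredoxin gene TSA2 (4.63 ± 0.09), the glutathione transferase gene GTT2 (3.81 ± 0.19) and the NADPH oxidoreductase gene OYE3 (3.14 ± 0.08). These 3 shifts were called (adjusted p = 1.05e-06, 1.32e-13 and 7.27e-07), but not with an estimated correlation (adjusted p = 0.445, 0.221 and 0.172).

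Ribosome biogenesis, polymerase, nitrogen, autophagy and proteasome genes moved with SMER1 in the direction seen with rapamycin. All 101 ribosome biogenesis factors fell, with a median of −1.40, as did all 20 polymerase I and III subunits, with a median of −1.29. KRR1 fell by 2.04 ± 0.15 and RPC25, a subunit of RNA polymerase III, by 2.20 ± 0.07. Of 22 nitrogen catabolite repression genes 17 rose, with a median of 0.69, PUT4 by 3.04 ± 0.11 and the general amino acid permease gene GAP1 by 2.44 ± 0.09. Of 24 autophagy genes 23 rose, with a median of 1.34, and of 33 proteasome genes 32 rose, with a median of 0.67. These 5 shifts were called (adjusted p = 5.54e-27, 7.92e-10, 0.000378, 3.96e-07 and 1.65e-08), and with an estimated correlation their adjusted p lay between 0.172 and 0.361.

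G1/S and purine genes fell with SMER1, as did part of the G2/M and ergosterol genes. Of 26 G1/S genes 21 fell and 0 rose, with a median of −1.07, including the cyclin gene CLB6 (−1.78 ± 0.08), the DNA polymerase alpha gene POL1 (−1.77 ± 0.15) and the mismatch repair gene MSH6 (−1.76 ± 0.09). Of 14 G2/M genes 8 fell, the mitotic cyclin gene CLB2 by 0.87 ± 0.20. The M/G1 and core histone lists (medians 0.03 and −0.03) were not called (adjusted p = 0.814 and 0.514). Of 16 purine genes 14 fell, ADE17 by 1.90 ± 0.09. Of 26 ergosterol genes 11 fell and 2 rose, the cytochrome b5 gene CYB5 falling by 1.84 ± 0.09 and the sterol desaturase gene ERG3 by 1.26 ± 0.09. The shifts of G1/S, G2/M, purine and ergosterol genes were called (adjusted p = 2.50e-08, 0.00887, 2.34e-06 and 0.00307; with an estimated correlation adjusted p = 0.268, 0.469, 0.329 and 0.403). The drug resistance list, targets of Pdr1 and Pdr3, rose in 9 of 14 members and the iron regulon in 12 of 23 (adjusted p = 0.00464 and 0.0173; with an estimated correlation 0.329 and 0.579). The reductase gene GRE2 rose by 2.83 ± 0.08, the multidrug transporter gene YOR1 by 1.26 ± 0.07 and the mitochondrial iron carrier gene MRS4 by 1.69 ± 0.11.

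The largest rises with SMER1 were those of YNL194C (6.10 ± 0.35), LSO1 (5.92 ± 0.41), the phosphatase regulator gene GIP2 (4.76 ± 0.32), SPG4 (4.73 ± 0.31), PHM7 (4.69 ± 0.15) and the hexose transporter gene HXT5 (4.68 ± 0.17). The pyruvate decarboxylase gene PDC5 rose by 3.96 ± 0.20. The largest falls included the adenine deaminase gene AAH1 (−2.96 ± 0.33), the mating-type endonuclease gene HO (−2.84 ± 0.16) and the phospholipase gene PLB2 (−2.22 ± 0.12). In all 3352 genes were called by limma, 1990 higher and 1362 lower, 595 and 384 of them at least 2-fold. Quantile normalisation shifted the median of all genes from 0.09 to −0.04 and gave 1706 higher and 1840 lower. Of the 31 lists, camera called 19, of which 0 held with an estimated correlation, and fry called 24.

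SMER1 and rapamycin shared 1583 genes called higher and 818 called lower against DMSO, where independent calls would share 791 and 278. A further 157 genes were called in opposite directions. The covariance of the log2 fold changes across genes was 0.529, against 0.0108 in simulated unchanged arrays, whose DMSO arrays were simulated too. For SMER2, SMER4 and SMER5, with 17, 0 and 0 genes called, the covariance with rapamycin was 0.0300, 0.0249 and 0.0405. Their correlations with rapamycin, 0.139, 0.174 and 0.218, lay below the 0.319, 0.318 and 0.315 of simulated unchanged arrays. Only the mean over the simulations was kept, so it gives no spread against which such small covariances could be judged. Genes are not independent replicates, and part of the excess of shared calls may come from the shared DMSO arrays.

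Against both DMSO and rapamycin, 1165 genes were called in the same direction with SMER1, 637 higher and 528 lower, and after quantile normalisation 664 and 660. Without SMER1 replicate 2 the count was 708. The genes higher than both references included 20 of 24 sulfur genes (17 to 20 when single arrays were left out), 27 of 30 stress genes (21 to 27) and 14 of 22 Yap1 targets. Those lower than both included 20 of 26 G1/S genes and 11 of 26 ergosterol genes (20 after quantile normalisation). None of the 101 ribosome biogenesis factors and 127 ribosomal protein genes was called against both by limma.

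SMER1 together with rapamycin gave the widest change among the comparisons with DMSO, with 3860 genes called by limma, 2159 higher and 1701 lower, 801 and 638 of them at least 2-fold (n = 2 treated and 3 DMSO arrays), and after quantile normalisation 1997 higher and 1909 lower. All 101 ribosome biogenesis factors fell, with a median of −2.74, including RRP36 (−4.42 ± 0.18), RIX1 (−4.02 ± 0.22), RRP8 (−3.79 ± 0.21) and PWP2 (−3.74 ± 0.22). All 20 polymerase subunits fell, RPA43 by 3.76 ± 0.21, and 85 of 127 ribosomal protein genes fell, RPL22B by 1.81 ± 0.09. All 22 nitrogen genes rose, with a median of 2.87, DAL80 by 6.47 ± 0.24 and PUT4 by 5.98 ± 0.11. All 30 stress genes rose, with a median of 3.08, and 21 of 24 sulfur genes rose while 2 fell, SUL1 rising by 3.98 ± 0.52. AAH1 fell by 4.19 ± 0.33, and the G1/S gene RNR1, a ribonucleotide reductase subunit, by 2.32 ± 0.08. The nitrogen shift was called (adjusted p = 6.65e-09) and held with an estimated correlation (adjusted p = 0.0343). The shifts of ribosome biogenesis, polymerase, ribosomal protein, stress and sulfur lists were called but lost with it (adjusted p = 0.354, 0.354, 0.526, 0.286 and 0.526). Camera called 20 lists and fry 25.

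Adding SMER1 to rapamycin, compared with rapamycin alone (n = 2 each), raised sulfur and stress genes and lowered G1/S, ergosterol and Gcn4 target genes. Of 24 sulfur genes 17 rose, MET2 by 2.33 ± 0.19, STR3 by 2.20 ± 0.33 and the homocysteine methyltransferase gene MHT1 by 2.07 ± 0.17. Of 30 stress genes 27 rose, ALD3 by 3.36 ± 0.20 and the catalase gene CTT1 by 2.22 ± 0.20. PDC5 rose by 4.23 ± 0.22, HXT5 by 3.84 ± 0.19 and the heat shock gene HSP30 by 4.41 ± 0.49. Of 26 G1/S genes 24 fell, RNR1 by 2.27 ± 0.09, the replication clamp gene POL30 by 1.86 ± 0.09 and the cyclin gene CLN2 by 1.72 ± 0.11. Of 26 ergosterol genes 23 fell, ERG5 by 1.44 ± 0.09, and of 36 Gcn4 targets 28 fell and 1 rose, ARG1 falling by 1.45 ± 0.13. Of 9 core histone genes 6 fell, HTB2 by 0.91 ± 0.10. These 6 shifts were called (adjusted p = 8.33e-09, 1.24e-15, 2.09e-09, 6.01e-08, 2.31e-06 and 0.0111) and not with an estimated correlation (adjusted p = 0.338, 0.178, 0.178, 0.178, 0.338 and 0.502).

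Many ribosome biogenesis, ribosomal protein and polymerase genes were lower when SMER1 was added: 89 of 101 biogenesis factors, 64 of 127 ribosomal protein genes and 16 of 20 polymerase subunits were lower than with rapamycin alone, with medians of −0.89, −0.29 and −0.58. RPF1 fell by 1.42 ± 0.12 and RPC25 by 1.68 ± 0.08. The 3 shifts were called (adjusted p = 5.17e-14, 5.11e-08 and 0.000686; with an estimated correlation 0.461, 0.624 and 0.513). Of 22 nitrogen genes 11 were lower and 2 higher, DAL1 by −2.84 ± 0.17 and the allantoin permease gene DAL4 by −2.79 ± 0.13. The nitrogen shift was called (adjusted p = 0.00908; with an estimated correlation adjusted p = 0.178) and was lost when the 25% of genes with the lowest mean were left out (adjusted p = 0.137). Of 18 genes of gluconeogenesis, the glyoxylate cycle and beta-oxidation 11 rose and 1 fell, the peroxisomal thiolase gene POT1 rising by 2.35 ± 0.34, and of 22 glucose transport and glycolysis genes 6 rose (adjusted p = 0.000180 and 0.00592; with an estimated correlation 0.205 and 0.460). In all 2527 genes were called by limma, 988 higher and 1539 lower, and 1643 without SMER1 and rapamycin replicate 2. Quantile normalisation gave 1221 higher and 1415 lower.

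The effect of SMER1 differed with and without rapamycin, by the interaction term, in 1401 genes, 241 with a positive and 1160 with a negative value. The nitrogen list had a median of −1.80, with 19 of 22 members negative, and this shift held with an estimated correlation (adjusted p = 9.86e-10 and 0.0269). DAL4 had an interaction of −3.48 ± 0.17, DAL1 of −3.06 ± 0.23 and GAP1 of −2.54 ± 0.14. Of 30 stress genes 29 were negative, with a median of −1.41, among them SOL4 (−2.82 ± 0.18) and DCS2 (−2.39 ± 0.12). Of 24 autophagy genes 17 were negative, APE1 at −2.11 ± 0.10. Ribosome biogenesis factors were positive in 28 of 101 cases, RRP5 at 2.38 ± 0.24 and UTP20 at 2.18 ± 0.21, and polymerase subunits in 11 of 20, RPA190 at 2.28 ± 0.18. PHM8 was at −3.03 ± 0.11. These other 4 shifts were called (adjusted p = 1.30e-13, 5.73e-06, 2.01e-22 and 1.85e-12), but not with an estimated correlation (adjusted p = 0.295, 0.295, 0.536 and 0.536). The median of all genes was −0.18 as deposited and −0.00 after quantile normalisation, which gave 562 positive and 732 negative. Without SMER1 and rapamycin replicate 1 or 2, or rapamycin replicate 1, the counts were 856, 816 and 911.

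Of the 2401 genes called in the same direction with each drug alone, 1153 changed with both drugs by less than the sum of the single log2 effects, and 0 by more. For those called higher with each drug, the median was 0.72 with SMER1, 0.67 with rapamycin and 0.87 with both, and for those called lower it was −0.81, −0.81 and −1.30. Selecting genes called with each drug alone favours a smaller value with both.

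**Figure D2:**
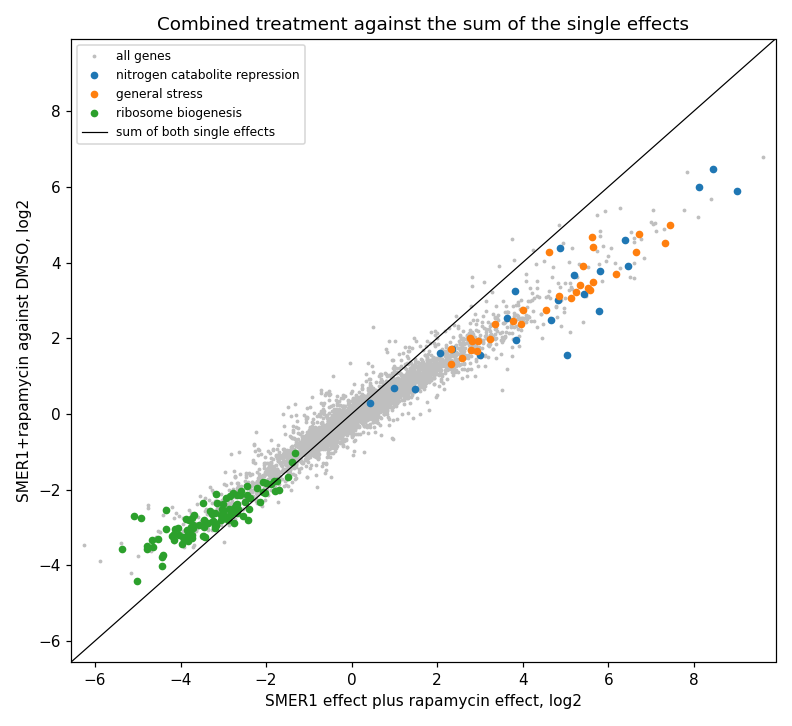
Log2 fold change against DMSO with SMER1 and rapamycin together (y axis) against the sum of the separate SMER1 and rapamycin effects (x axis); each point is 1 of 5449 genes, with nitrogen, stress and ribosome biogenesis genes coloured and the line marking equality. The nitrogen genes lay below the line by a median of 1.80, and 0 of the 1153 genes that departed from it among the 2401 shared ones changed by more than the sum.

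Some phosphate genes were lower in the SMER2 array than in DMSO, and few others passed the test (n = 1 array). Limma called 17 genes, 5 higher and 12 lower, and 476 had an unadjusted p under 0.05. The sodium-phosphate cotransporter gene PHO89 fell by 2.44 ± 0.16, and 3 more targets of Pho4, the phosphate starvation factor, fell: PHM6 by 1.38 ± 0.15, the acid phosphatase gene PHO5 by 1.07 ± 0.14 and SPL2 by 1.01 ± 0.13. Among 16 measured phosphate genes 4 were called (8 adjusted over the list alone), and the list median of −0.50 lay below all 10000 random lists. These lists were matched on expression only, so the placement does not allow for genes that move together on 1 array. GRE2 rose by 0.86 ± 0.10, the lipid acyltransferase gene ICT1 by 0.69 ± 0.09, SRL3 by 0.68 ± 0.07, and the chaperone genes HSP78 and HSP104 by 0.57 ± 0.07 and 0.55 ± 0.08. Camera called 8 lists, of which 0 held with an estimated correlation. Among them, the sulfur, Gcn4 and proteasome lists (medians −0.17, 0.07 and 0.07) also lost their call with a replicate block. The phosphate, drug resistance, Hsf1, retrograde and purine shifts were called (adjusted p = 3.53e-14, 4.06e-12, 9.68e-10, 0.000199 and 0.000199; with an estimated correlation 0.315, 0.0826, 0.339, 0.799 and 0.811), and fry called the phosphate and drug resistance lists.

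The number of genes called with SMER2 changed when other arrays were left out. Without DMSO replicate 1, 2 or 3 it was 5, 7 and 3, without any 1 of the 4 arrays with SMER1 it was 2, and without either rapamycin array it was 4. After quantile normalisation it was 11, of which 5 were higher and 6 lower. With a replicate block it rose to 513, with all 17 genes of the main fit among them, though the replicate numbers were not taken to pair the arrays. The block assumes that the SMER2 array shares an offset with the other arrays numbered 1. That array correlated less with DMSO replicate 1 (0.9853) than with replicates 2 and 3 (0.9887 and 0.9899). PHO89 was called in every one of these fits. The other genes named for SMER2 were not, and YEL075C, a subtelomeric open reading frame that fell by 1.53 ± 0.10, was lost after quantile normalisation. PHO89 fell further with rapamycin than in the SMER2 array, and GRE2 also rose with rapamycin (0.71 ± 0.08). Neither these genes nor PHM6, PHO5 and SPL2 were called against both DMSO and rapamycin in the main fit. Against both DMSO and rapamycin 8 genes were lower, YEL075C, DAK2, NUT2, PDH1, YLR156W, YHK8, YHR210C and IDH1, and 0 were higher. That count was 3 after quantile normalisation, with 2 higher and 1 lower, and between 1 and 3 without single arrays: 3 without DMSO replicate 1 or 2, 2 without DMSO replicate 3 or a rapamycin array, and 1 without an array with SMER1.

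Stress, sulfur, Yap1, drug resistance and Hsf1 target genes were higher in the SMER3 array than in DMSO (n = 1 array). All 30 general stress genes rose, with a median of 1.61, including XBP1 (4.12 ± 0.27), CTT1 (3.96 ± 0.23) and ALD3 (3.40 ± 0.23). Of 24 sulfur genes 21 rose, with a median of 1.50, among them STR3 (4.53 ± 0.39), the regulator genes MET32 (3.53 ± 0.36) and MET28 (3.39 ± 0.27), and MET2 (3.25 ± 0.22). Of 22 Yap1 targets 18 rose, with a median of 1.20, OYE3 by 5.21 ± 0.10, the sulfiredoxin gene SRX1 by 5.09 ± 0.16 and TSA2 by 4.13 ± 0.11. Of 14 drug resistance genes 12 rose, RSB1, a sphingoid base transporter gene, by 4.32 ± 0.25 and CIS1 by 3.95 ± 0.10. Of 19 targets of Hsf1, the heat shock factor, 13 rose, BTN2 by 3.55 ± 0.16 and the Hsp70 gene SSA4 by 3.18 ± 0.21. The 5 shifts were called (adjusted p = 4.65e-14, 3.80e-09, 2.10e-10, 3.33e-08 and 5.70e-07), but not with an estimated correlation (adjusted p = 0.260, 0.373, 0.108, 0.108 and 0.308).

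Part of the G1/S, G2/M and M/G1 genes were lower in the SMER3 array. Of 26 G1/S genes 13 fell, including the cyclin genes PCL1 (−2.67 ± 0.08) and CLN1 (−1.42 ± 0.08) and the replication licensing gene CDC6 (−2.01 ± 0.22). Of 14 G2/M genes 7 fell, CLB2 by 2.56 ± 0.26, and of 14 M/G1 daughter genes, expressed at cell separation, 6 fell, SCW11 by 1.40 ± 0.11. Of 101 ribosome biogenesis factors 33 fell, with a median of −0.48, and of 20 polymerase subunits 10 fell, with a median of −0.46. Autophagy genes rose in 14 of 24 cases, ATG8 by 2.06 ± 0.11, respiration genes in 14 of 35, CYC1, a cytochrome c gene, by 1.69 ± 0.14, and meiosis and sporulation genes in 10 of 19, SPO11 by 2.50 ± 0.30. The 8 shifts were called (adjusted p = 1.11e-06, 0.000553, 0.000988, 2.10e-10, 3.10e-05, 1.86e-05, 0.00233 and 0.000224). With an estimated correlation their adjusted p lay between 0.260 and 0.661.

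The largest rises with SMER3 were those of YCR102C (5.65 ± 0.37), YKL070W (5.63 ± 0.47), HSP30 (5.25 ± 0.57) and OYE3. The falls included BSC1 (−3.96 ± 0.92) and the multidrug transporter gene AQR1 (−2.84 ± 0.30). Limma called 1983 genes, 1177 higher and 806 lower, 474 and 149 of them at least 2-fold. Quantile normalisation moved the median of all genes from 0.02 to −0.09 and gave 1016 higher and 1283 lower. SMER3 shared 802 higher and 337 lower calls with rapamycin (468 and 164 if independent), with 252 opposite. The covariance with the rapamycin fold changes across genes was 0.259, against 0.0109 in simulated unchanged arrays. Against both DMSO and rapamycin 993 genes were called, 531 higher and 462 lower, and after quantile normalisation 513 and 698. They included, as higher, 17 of 24 sulfur genes, 13 of 22 Yap1 targets, 11 of 14 drug resistance genes and 10 of 19 Hsf1 targets, and, as lower, 13 of 26 G1/S genes.

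No gene passed the threshold with SMER4 or SMER5 in the main fit (n = 1 array each), which does not show that none changed. Limma called 0 genes for each, with 78 and 211 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.137 and 0.0811. Against both DMSO and rapamycin limma also called 0 genes for each. GRE2 was at 0.76 ± 0.10 in SMER4 and 0.89 ± 0.10 in SMER5 (adjusted p = 0.172 and 0.0811). It also rose with rapamycin, by 0.71 ± 0.08 (limma adjusted p = 0.000183), so a rise of this size was not particular to the SMERs. All of these differences were taken from the same 3 DMSO arrays. The drug resistance list was called in both, with medians of 0.16 and 0.33 (adjusted p = 4.86e-05 and 1.62e-12; with an estimated correlation 0.471 and 0.0727), with 1 and 6 of 14 members higher adjusted over the list alone. The stress list was called in SMER5 with a median of 0.19 (adjusted p = 1.37e-06; with an estimated correlation 0.872). Fry called 0 lists in SMER4, and in SMER5 the drug resistance list (adjusted p = 0.0123). The gene counts changed under some alternatives. With a replicate block SMER5 had 82 called genes, 40 higher and 42 lower, and SMER4 had 0. The replicate numbers were not taken to pair the arrays, and the SMER5 array correlated less with DMSO replicate 1 (0.9845) than with replicates 2 and 3 (0.9923 and 0.9914). SMER5 had 1 called gene, GRE2, when the genes with the lowest mean were left out, and again with an intensity trend. With only the arrays of the groups compared, SMER4 had 1 called gene, YGL235W, and SMER5 had 0. Without DMSO replicate 2 each SMER had 1 called gene, DAK2, at 1.36 and 1.25, a gene named after its values were seen.

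**Figure D3:**
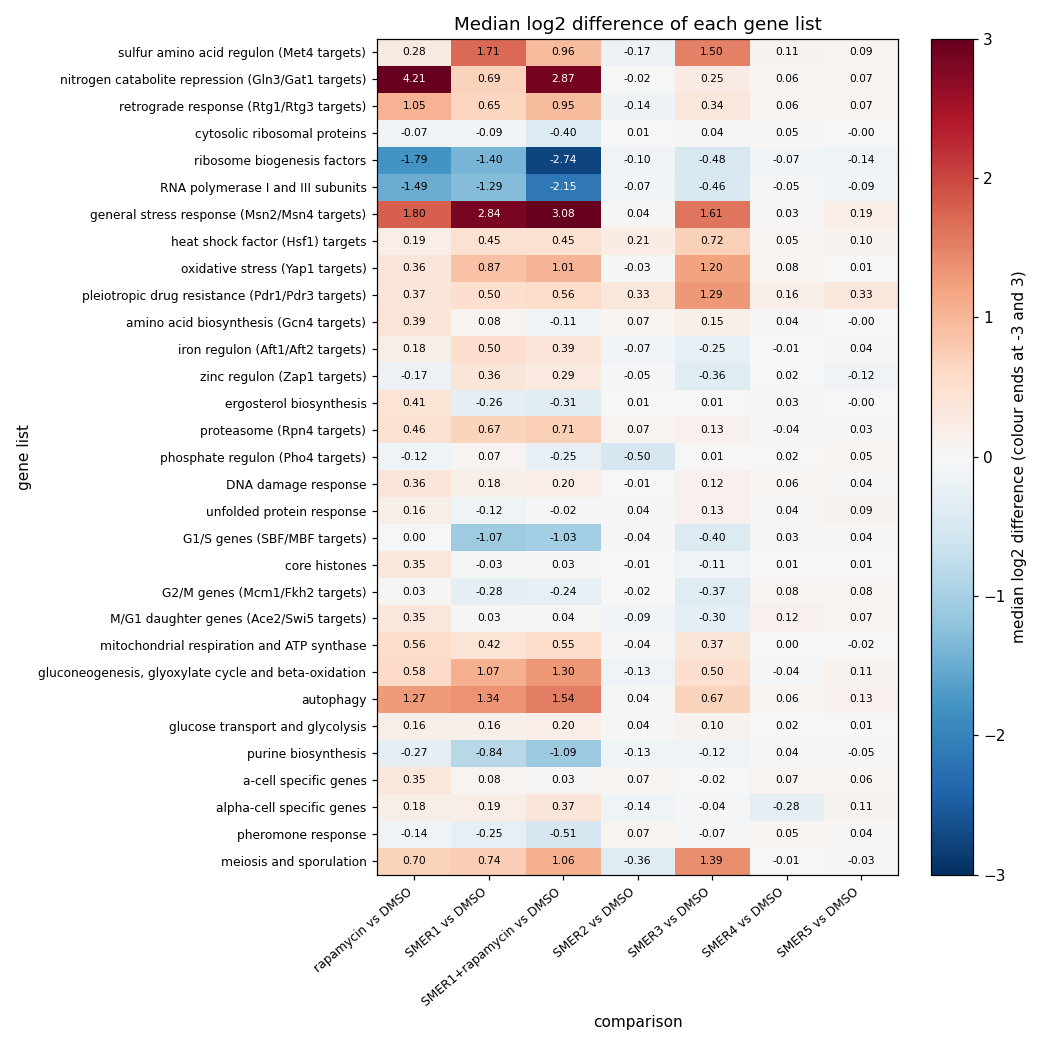
Median log2 fold change of each of 31 gene lists (y axis) in the 7 treatments against DMSO (x axis), coloured by log2 value. The largest list median was 4.21, for nitrogen genes with rapamycin, and the lowest was −2.74, for ribosome biogenesis factors with SMER1 and rapamycin.

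The 5 SMERs, given at the same dose and time, differed in 3165 genes by the moderated F test. Of these 2770 were called with SMER1, 1771 with SMER3 and 61 with neither. The smallest p values were those of OYE3, TSA2, DCS2, PHM8, YNL195C, ATO2, GCY1, FMP33, GPH1 and FMP48. OYE3 was at 7.59 in DMSO, 10.73 in SMER1, 7.52 in SMER2, 12.80 in SMER3, 7.49 in SMER4 and 7.42 in SMER5.

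SMER3 and SMER1 differed directly in 2542 genes, 1122 higher and 1420 lower in SMER3 (n = 1 and 2 arrays), and after quantile normalisation 1268 and 1435. Ribosome biogenesis factors were higher in SMER3 in 76 of 101 cases, with a median of 0.92, and purine genes in 13 of 16, with a median of 0.72. Stress genes were lower in 23 of 30 cases, with a median of −0.91, proteasome genes in 29 of 33, with a median of −0.49, and iron genes in 12 of 23, with a median of −0.62. The 5 shifts were called (adjusted p = 1.25e-15, 2.48e-05, 3.29e-07, 1.07e-07 and 0.000962), but not with an estimated correlation (adjusted p = 0.630 for each). The sulfur list was not called as different (adjusted p = 0.859), and 8 of its 24 members were. The methionine permease gene MUP3 was 1.65 ± 0.29 higher and SUL1 2.54 ± 0.70 lower in SMER3. MET2 differed by −0.03, with a 95% interval from −0.57 to 0.51. Both compounds shared 902 higher and 441 lower calls against DMSO (430 and 201 if independent), with 169 opposite and a covariance across genes of 0.407 (0.0109 in simulated unchanged arrays).

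No difference between SMER4 and SMER5 passed the threshold in limma (0 genes called, 63 at an unadjusted p under 0.05), with a median 95% interval of ±0.355 around each difference. GRE2 differed by −0.13, with a 95% interval from −0.41 to 0.15, and PHO89 by −0.19, with an interval from −0.65 to 0.26. These intervals leave room for differences of that size.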

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

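The interaction was planned, and the tests of explanations in this part were all chosen only after the results were seen.

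The effect of SMER1 differed with and without rapamycin in 1401 genes by the test of the difference itself. The same test marked the nitrogen list (median −1.80), the ribosome biogenesis list (0.52), the stress list (−1.41) and the autophagy list (−0.84), and the genes DAL4 (−3.48), PHM8 (−3.03), RRP5 (2.38) and RPA190 (2.28). With an estimated correlation the nitrogen list held (adjusted p = 0.0269) and the other 3 were lost (adjusted p = 0.536, 0.295 and 0.295).

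Among the 2401 genes changed the same way by each drug, 1153 changed with both by less than the sum of the log2 effects, and 11 nitrogen genes were lower with both drugs than with rapamycin alone. A ceiling or floor of the arrays as the whole cause for the 1153 genes is argued against by their additive expectations. These lay beyond the middle 98% of all values in 16.3% of the 1153 genes. A ceiling alone stops a rise but gives no drop, so it would not put the 11 nitrogen genes lower. That count is the pattern itself, not a separate test, and does not bear on the 1153 genes. Scaling between arrays as the whole cause is argued against by the 72.7% of the 1153 genes still called after quantile normalisation. The 11 nitrogen genes also stayed called lower. The call was kept by 644 of the 958 genes higher with each drug and by 194 of the 195 lower ones. Scaling stays open for part of the higher genes. Genes that changed by more than the sum were not recounted after quantile normalisation. A milder compression of bright signals was not tested and stays open, and selecting genes called with each drug alone favours such calls. Responses that share a limit, and an effect of SMER1 on the nitrogen response to rapamycin, may account for the pattern as hypotheses, which 1 dose of each drug leaves untested.

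The rise of the sulfur genes with SMER3 (median 1.50) rests on 1 array. Drift between arrays is argued against by the largest gap of this list's median between arrays of 1 group, 0.318. A mislabelled SMER1 array is argued against by the highest correlation with a SMER1 array, 0.917, which lies under the lowest within a group, 0.984. A stress response that carries the sulfur genes along in a fixed proportion is argued against by the ratio of the sulfur to the stress median, 0.155 in rapamycin and 0.934 in SMER3, but the ratio of 0.602 in SMER1 leaves open such a response of the kind seen with SMER1. An effect of SMER3 may account for the rise, as a hypothesis, and an unusual single culture stays open.

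The fall of the phosphate genes with SMER2 (median −0.50) also rests on 1 array. Ordinary variation of phosphate state between cultures is argued against by the largest departure of the list median among the DMSO, SMER4 and SMER5 arrays, −0.123, although only 5 arrays could show it. Rapamycin in the SMER2 sample is argued against by the nitrogen list, whose median was −0.0183 in SMER2 and 4.21 in rapamycin. The fall was not particular to SMER2 at PHO89, which fell further with rapamycin, although the list median with rapamycin was −0.12. An effect of SMER2 may account for the fall of the list, as a hypothesis, and a single culture with an unusual phosphate state stays open.

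The 218 probe sets without a gene name, which the comparisons left out, also held signals that differed from DMSO: 137 were called with rapamycin, 143 with SMER1 and 100 with SMER3 when they were added to the fit.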

How the results depend on the processing

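The alternatives were planned, except those for SMER3 against SMER1, SMER4 against SMER5 and the list tests of the first of these and of the interaction, which were chosen after the results were seen. The total counts for rapamycin, SMER1, SMER3 and both drugs against DMSO, the F test and SMER3 against SMER1 stayed within 1.5 times their values under every alternative run. The balance of directions was less stable. For SMER1 and SMER3 against DMSO, more genes were called higher than lower as deposited, and more lower than higher after quantile normalisation. After quantile normalisation SMER2 had 11 called genes, and 3 against both references. Leaving out the 25% of genes with the lowest mean gave 1 called gene (GRE2) for SMER5 and 3 for SMER2 against both references, and an intensity trend gave 1 (GRE2) and 3. With only the arrays of the groups compared, SMER2 had 2 called genes (PHO89 and YIR021W-A), SMER4 had 1 (YGL235W) and SMER2 against both references 1 (YEL075C). The single genes named here were chosen after their values were seen. With a replicate block the counts were 513 for SMER2, 82 for SMER5, 2377 for the interaction, and against both references 313 for SMER2, 1615 for SMER3 and 56 for SMER5. Deviations of arrays sharing a number correlated at 0.0705, 0.131 and 0.0848 with DMSO replicate 2 and from 0.430 to 0.598 otherwise, equal by construction for both replicates of groups of 2. Since not every value was over 0.1 the numbers were not taken to pair the arrays, and a batch shared by the other arrays stays open. The lone arrays all carry number 1 and leave no deviations, so these values do not show whether they belong to such a batch. The SMER2, SMER4 and SMER5 arrays correlated less with DMSO replicate 1 (0.9853, 0.9884 and 0.9845) than with replicates 2 and 3 (0.9887 to 0.9952). The SMER3 array correlated slightly more with replicate 1 (0.9154 against 0.9132 and 0.902). The main fit counts any variation shared by arrays of the same number as error. With single arrays left out the counts ranged from 2 to 7 for SMER2, 0 to 1 for SMER4 and SMER5 (DAK2, without DMSO replicate 2), 1643 to 2606 for both drugs against rapamycin (1643 without SMER1 and rapamycin replicate 2), 816 to 1426 for the interaction (856 and 816 without SMER1 and rapamycin replicate 1 and 2, 911 without rapamycin replicate 1), and against both references 708 to 1156 for SMER1 (708 without SMER1 replicate 2) and 1 to 3 for SMER2. Fewer arrays lower the residual degrees of freedom, and the cause of the other changes was not tested. Of the 102 list shifts called in the planned comparisons, 2 held with an estimated correlation. Reversed were the ribosome biogenesis list in SMER4 with the block (0.0118) and, after quantile normalisation, PIR1, SMER1 vs DMSO (−0.0695) and the interaction of GEX1 (0.0701), RNR2 (0.0182) and IME2 (0.142). Of 128 called list shifts, 116 kept their call and direction after quantile normalisation, 113 of 127 with the 25% of genes with the lowest mean left out, 127 of 128 with the trend, 115 with the block (the Gcn4 list with rapamycin lost, adjusted p = 0.0685), and 122 to 128 without single arrays. The comparison of SMER4 with SMER5 on its own arrays was not run, since no residual degrees of freedom remain, and an offset before taking logs was not run, since the values were already on the log2 scale. Genes near the array's background, such as the 103 with a mean below 5, have the least precise values.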

Other observations

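The tests in this part were chosen after the results were seen, except that the prediction for the chromosome ends was written before its result.

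Among 30 gene families picked by name after the data were seen, 46 of 55 mitochondrial ribosomal protein genes rose with SMER1 (median 0.42; adjusted p = 0.15 with an estimated correlation), and 43 were lower in SMER3 than in SMER1 (median −0.53; adjusted p = 0.153 with an estimated correlation). With rapamycin 30 of them rose and 1 fell (median 0.21), and with both drugs 45 rose (median 0.39), with adjusted p = 0.758 and 0.241 with an estimated correlation. All 12 trehalose and glycogen enzyme genes rose with rapamycin (median 1.31), SMER1 (2.11), SMER3 (0.77) and both drugs (2.33), with adjusted p = 0.388, 0.15, 0.189 and 0.197 with an estimated correlation. The trehalose synthesis gene TSL1 rose by 1.43 ± 0.08 with rapamycin and 2.35 ± 0.08 with SMER1. Of 23 translation initiation factor genes 18 fell with rapamycin (median −0.60) and 18 with SMER1 (median −0.47), with adjusted p = 0.398 and 0.478 with an estimated correlation. TIF5 fell by 1.10 ± 0.06 with rapamycin and 0.71 ± 0.06 with SMER1.

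PDC5 and PDC6, pyruvate decarboxylase genes, rose by 3.96 and 2.31 with SMER1, were at 0.50 and −0.18 with SMER3 (adjusted p = 0.161 and 0.560), and were lower in SMER3 than in SMER1 by −3.46 and −2.49. Of 13 seripauperin genes, a subtelomeric family of near-identical members, 9 rose with SMER3 (median 1.32; adjusted p = 0.209 with an estimated correlation), PAU4 by 2.04 ± 0.12. With SMER1 3 rose and 1 fell (median 0.09), and 7 were higher in SMER3 than in SMER1 (median 1.28; adjusted p = 0.236 with an estimated correlation). STE3, the a-factor receptor gene of alpha cells, rose by 1.35 ± 0.17 with rapamycin and 1.43 ± 0.17 with SMER1. Its DMSO mean of 6.91 lay below that of LEU2 (7.96), a marker gene altered in this strain, so its signal may lie near background.

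The hypothesis that genes near chromosome ends fall as a class with SMER3 was tested on the 10 outermost genes of each arm. Of 224 such genes measured 26 were called lower (11.6%), against 780 of 5225 others (14.9%), with a one-sided permutation p of 0.932 over 100000 permutations, so no excess was found. Of these genes 63 were called higher (28.1%), against 1114 others (21.3%), which was not tested.

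For 47 genes the array held further probe sets, 49 in all. A further probe set and the one kept were both called in the same direction in 9 cases with rapamycin, 10 with SMER1, 8 with SMER3 and 22 with both drugs against DMSO, and in 13 with both drugs against rapamycin, while only 1 of the pair was called in 16, 17, 12, 17 and 19. Their calls opposed those of the probe set kept in 1 case in the comparison of both drugs with DMSO and in 0 cases in the other comparisons examined.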
